A study of Mus musculus with 6 samples.

How the data were processed

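Total RNA from soleus muscle of male mice was measured on Affymetrix mouse expression arrays, 1 array per sample. The labels name 3 wild-type C57BL/6 samples and 3 samples of mice lacking estrogen receptor beta, whose strain they do not give. Replicates are numbered in the order of deposit, and equal numbers also have adjacent title numbers, so the labels leave open whether samples were paired. The labels do not say that each sample came from its own animal, so the p-values measure only the spread among these samples.

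The values used were the authors' deposited signal intensities on a linear scale, 1 value per probe set and array. The software that made them is not given in the sources used here, and the deposited values carry no detection calls. The mean intensity without the lowest and highest 2% of values was 100.07 on each deposited array, so the authors' scaling to a common level was kept. No scanner images or probe-level values were used here, so background correction and summarisation could not be varied. A fixed total also means that a rise of the most abundant transcripts can lower the values of others on the same array.

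Of 12488 probe sets, 66 controls were set aside. The annotation table of the array design gave exactly 1 gene symbol to 10833 of the other 12422 probe sets, several to 396 and none to 1193, and a look-up in a RefSeq table of assembly GRCm38.p6 changed 0 of the symbols. Only probe sets with 1 symbol were named. Positions from that table were used only to find which genes neighbour each other.

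Values under the 20th percentile of all values, 7.8, were set to that floor and all values were taken to log2. A probe set was tested if it exceeded the median of all values, 39.4, on at least 3 of the 6 arrays, whatever the group, which left 6369 probe sets for 4921 genes. Knockout minus wild type was tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision: the median standard error of a log2 difference was 0.18, and an exact two-sided permutation test of 3 against 3 cannot go below p = 0.1.

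Before the data were examined, 25 gene lists were fixed for fibre types, metabolism, stress, matrix, hormone response and the other cell types a muscle sample can hold. The 24 lists with at least 5 tested members were compared with all other genes by limma's camera at its preset correlation of 0.01, using the probe set with the highest mean for each gene. Camera with an estimated correlation and fry were run beside it, and adjusted p-values are over the 24 lists. The place of each list's median among 10000 random lists was also computed, matched on signal by 20 groups of genes of equal size. Members are given as adjusted over the list alone and over all probe sets.

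The genes named follow a rule fixed before the data were examined. It takes both estrogen receptors, and up to 12 genes per direction by size of difference, filled from probe sets at an unadjusted p under 0.01 with groups that do not overlap when none passes the adjusted threshold. It also takes up to 4 members of each list with the smallest p, and genes within 10 Mb of Esr2 at an unadjusted p under 0.05. Xist and the Y-linked genes were read to check the sex. Hoxd1, Tuba1a, Atp2a1, Tnnc2, Pvalb, Myh1, Myh7 and the further probe sets of named genes were chosen after their values were seen. Genes near Esr2 were compared with all others by Fisher's exact test.

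The alternatives were quantile normalization, scaling to a common median, floors at the 5th and 40th percentiles, no filter and a filter at the 70th percentile, eBayes without the trend or made robust, array weights, and leaving out each array. The prefix of the sample titles, shared by 4 arrays and by the other 2, and adjacent title numbers were each used as a block. Cyclic loess and a fit of the 4 arrays sharing a prefix were added after seeing the data. The direction of a list under an alternative was read from the sign of its median. This was settled after the counts were known: 38 of 452 list values then reversed, against 29 if camera's direction is used.

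The steps were tested on simulated data drawn from the real means and spreads. Among 6331 probe sets, limma recovered 90 of 92 changed 4-fold and 67 of 91 changed 2-fold, with 13 false calls among 170. Camera recovered 2 of 2 lists shifted by 0.3 on the log2 scale and made 0 false calls among the others. Simulated genes were independent of each other, unlike real ones. The 92 and 91 are the changed probe sets that passed the filter, and those it removed are not counted. Many probe sets were changed at once, which eases the adjusted threshold, so these shares need not hold where few genes differ.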

Results

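The series addresses skeletal muscle of males and females and the role of estrogen receptor beta, the nuclear receptor encoded by Esr2. The samples analysed here were all from males. Soleus, a postural muscle of mainly slow and oxidative fibres, was compared between 3 wild-type samples and 3 samples of Esr2 knockout mice. Each array gave 12488 values. The array medians were 40.2 ± 0.37 in wild type and 38.4 ± 1.42 in the knockout (SD, n = 3 each; exact permutation p = 0.1, the smallest this design allows). Arrays correlated with each other at r between 0.948 and 0.966 across probe sets, which are not independent replicates. The first principal component, 27.0% of the variance, set knockout replicate 2 apart, and the next, 23.8%, set wild-type replicate 2 apart. The groups separated on the component after these, with 19.1%. The 2 arrays set apart, replicate 2 of each group, are the 2 that share the smaller title prefix. What that prefix stands for is not given. The ratio of 3' to 5' Gapdh control signals, a sign of RNA integrity, was 1.06 ± 0.07 in wild type and 0.98 ± 0.05 in the knockout (SD, n = 3 each; exact permutation p = 0.2).

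No probe set of either estrogen receptor gene passed the filter, so none was tested. The Esr2 probe set read 2.2, 3.2 and 1.3 in wild type and 8.4, 3.9 and 6.2 in the knockout, and 5 of the 6 values lay at or below the floor of 7.8. These readings did not overlap between the groups, but at this level they are not a measure of transcript. The labels could therefore not be checked from the targeted gene, and it is not known whether the probes lie in the deleted part. The 4 probe sets of Esr1, the gene of estrogen receptor alpha, read between 4.0 and 26.3, below the filter on all 6 arrays, and 1 of them was lower in the knockout without overlap (17.9 ± 7.66 to 9.77 ± 1.10; SD, n = 3 each). The others overlapped, with wild-type and knockout means of 10.1 and 8.9, 5.7 and 7.6, and 6.2 and 7.3. At this level the Esr1 readings are not a measure of transcript either. Xist, expressed from the inactive X chromosome of females, read between 2.2 and 8.2. The Y-linked gene Eif2s3y read between 78.9 and 130.6, and Uty between 21.0 and 37.6, while Kdm5d was near the floor at 5.9 to 12.1.

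With the settings described above, no single gene passed the adjusted threshold over all probe sets. Of 6369 probe sets, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.923. At an unadjusted p under 0.05 there were 334 probe sets, 179 higher and 155 lower in the knockout, against 318 expected by chance. At under 0.01 there were 55, against 63.7 expected. The groups did not overlap for 680 probe sets, 10.7%, where chance gives 10%. Under other settings 1 probe set passed in each of 3 cases: Myh4 with adjacent title numbers as a block, Tuba1a without knockout replicate 1 (adjusted p = 0.0412) and Hoxd1, near the floor, without the filter (adjusted p = 0.024).

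The genes with the largest differences are given as values, and none passed the adjusted threshold (adjusted p = 0.923 for each of these 24 genes). Ache, the acetylcholinesterase of the neuromuscular junction, read 21.3 ± 6.40 in wild type and 57.9 ± 20.8 in the knockout (SD, n = 3 each), a ratio of 2.71. Ada, adenosine deaminase, went from 42.0 ± 8.48 to 92.3 ± 29.2, and Ogg1, a DNA glycosylase for oxidised guanine, from 37.5 ± 1.55 to 78.5 ± 26.7. Ncam1, a neural cell adhesion molecule, read 38.5 ± 2.52 and 64.6 ± 9.58. The ratios of the splicing factor Rbfox2, the calcium channel subunit Cacnb2 and the homeobox genes Six4 and Pitx3 were 1.82, 1.76, 1.64 and 1.58. Rhoa stood at 1.73, Dnal4 at 1.62, Mid1ip1 at 1.59 and Cmbl at 1.53. In the other direction, the log2 difference was -2.09 ± 0.41 (SE) for Larp7, -1.86 ± 0.43 for Atad3a, a mitochondrial membrane protein, and -1.71 ± 0.36 for Pea15a. In wild type Larp7 read 48.8 to 95.7, Atad3a 51.2 to 63.5 and Pea15a 51.5 to 94.1. In the knockout they read 11.1 to 21.9, 11.2 to 28.2 and 16.1 to 29.7, below the filter on each knockout array. The size of these decreases is therefore uncertain. The same holds for the increases of Ache, Ogg1 and Cacnb2, which lay below the filter on each wild-type array. In wild type they read 13.9 to 25.5, 35.9 to 39 and 29.1 to 34.2. Actn3, the actinin of fast glycolytic fibres, followed at -1.16 and carbonic anhydrase Car4 at -1.06. Ddx27 (-0.80), Hsd3b7 (-0.72), Ipo7 (-0.67), Zkscan1 (-0.67), Gcdh (-0.67), Cul2 (-0.66) and Tns2 (-0.61) followed. Other probe sets did not always show the same difference: those of Rhoa gave -0.05 and -0.02, those of Six4 0.25 and 0.04, that of Larp7 -0.20, that of Car4 0.06 and that of Gcdh 0.06, while the other Actn3 probe set gave -1.48.

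Contractile genes of both fibre types were mostly higher in the knockout, but the heavy chains Myh7 and Myh1 were nearly level and Myh4 and Actn3 were far lower. Of 24 gene lists 9 passed camera at the preset correlation, and 0 passed with an estimated correlation or in fry. With an estimated correlation 0 lists passed under each of the 19 alternatives as well, and the lowest adjusted p there was 0.238. The list members named had an adjusted p of 0.923 to 0.995 over all probe sets. Of 13 slow fibre genes 11 were higher, with a median log2 difference of 0.21 (camera adjusted p = 8.5e-06; adjusted p = 0.285 with an estimated correlation). Csrp3, a Z-disc protein, went from 1054 ± 477 to 1814 ± 594 (SD, n = 3 each), and Ankrd2, a stretch-responsive protein, from 2425 ± 792 to 3569 ± 530. Fhl1 and the light chain Myl3 stood at ratios of 1.26 and 1.16. Over the slow list alone 0 members passed. Of 13 fast fibre genes 10 were higher (camera adjusted p = 0.0108, upward; adjusted p = 0.285 with an estimated correlation). The median of that list was 0.23 but its mean was -0.18. Adjusted over the list alone, 7 fast members passed (adjusted p = 0.0331 to 0.041), and 0 passed over all probe sets. The median of the slow list lay at the 99.3 percentile and that of the fast list at the 99.9 percentile of random lists matched on signal. Of these, the calcium store protein Casq1 (2770 ± 428 to 3671 ± 98.8), the light chain Myl1, the troponins Tnnt3 and Tnnc2 and the calcium pump Atp2a1 were higher. Myh4, the heavy chain of type IIb fibres, and Actn3 were lower. Among members that did not pass over their list alone, the heavy chains Myh7 (slow list) and Myh1 (fast list) had log2 differences of 0.069 and 0.0044. Both count among the higher members. Pvalb of the fast list stood at -0.32. Myh4 read 1610, 3671 and 499 in wild type and 211, 791 and 73.8 in the knockout, a log2 difference of -2.64 ± 0.86 (SE). Myosin heavy chain paralogs are similar in sequence, so the identity of this signal is uncertain. With adjacent title numbers as a block Myh4 had an adjusted p of 0.00313, in a range of 0.00313 to 0.999 over its alternatives, and the labels do not say that such numbers pair mice. After quantile normalization the medians of the slow and fast lists were 0.00075 and 0.0015 and neither passed, and Myl3 and Tnnt3 stood at -0.025 and -0.0070. Without wild-type replicate 3 the fast list did not pass (adjusted p = 0.143), nor did it with adjacent title numbers as a block (adjusted p = 0.193; range 0.00129 to 0.804 over the alternatives), while the slow list passed whichever array was left out, with a median from 0.096 (without wild-type replicate 1) to 0.29.

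**Figure D1:**
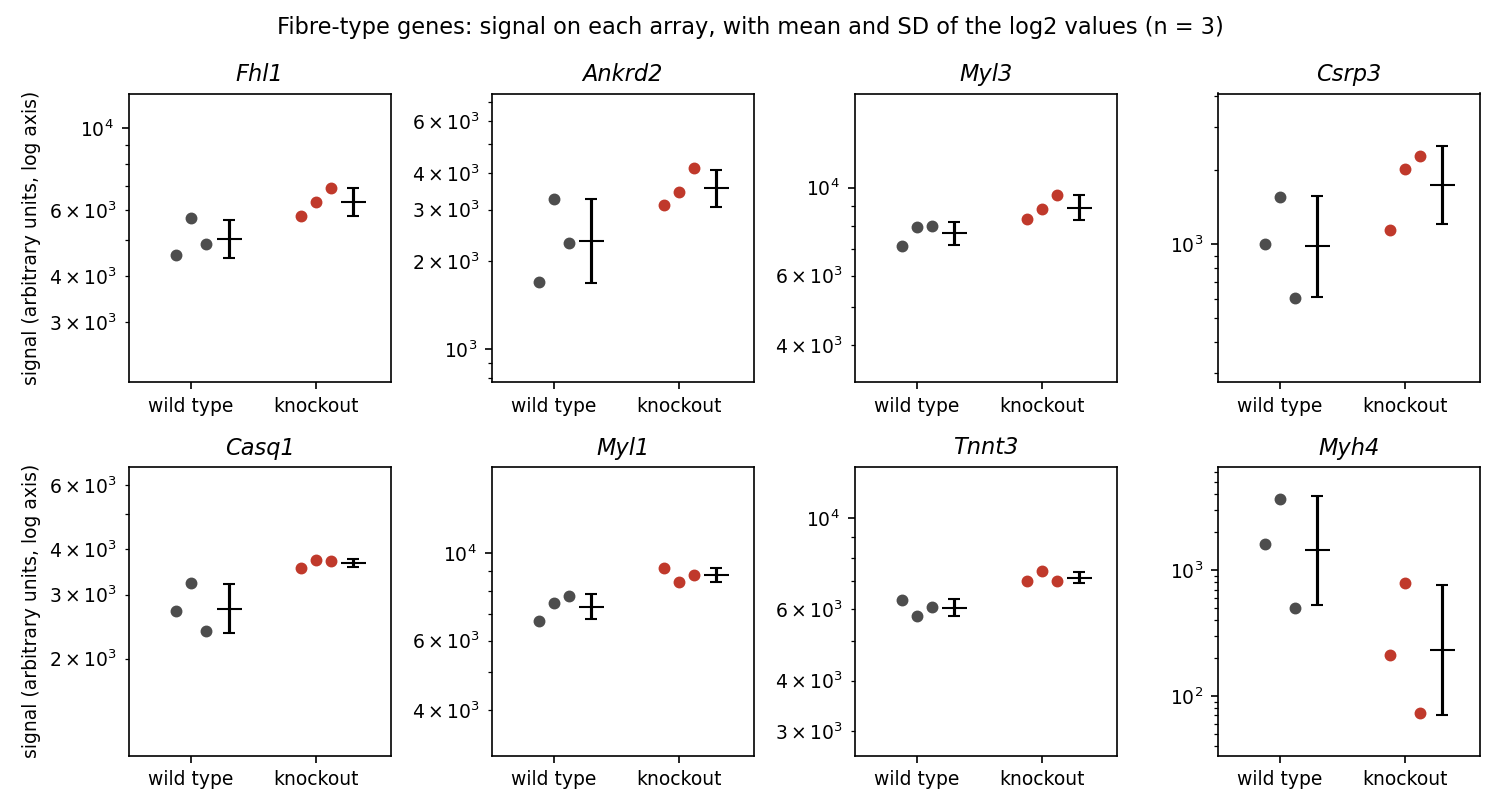
Signal on each array (arbitrary units, log axis) of the 4 slow fibre genes (top) and 4 fast fibre genes (bottom) with the smallest p in their lists; dots are arrays, and the black mark and bar are the mean and SD of the log2 values of 3 arrays. Myh4 spans 73.8 to 3671 and overlaps between the groups, whereas Casq1, Myl1 and Tnnt3 do not overlap.

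Among other muscle lists none passed with the settings described above. Of 13 sarcomere and costamere genes 8 were higher, with a median of 0.02 (camera adjusted p = 0.0552), among them myoglobin Mb (ratio 1.20), skeletal actin Acta1 (1.22), Actn2 (1.48) and Sgca (1.10). Calcium handling genes had a median of 0.06 (adjusted p = 0.069), with Ryr1, the calcium release channel, at 1.13, Cacng1 at 1.23, Cacna1s at 1.17 and the chloride channel Clcn1 at 1.26. Developmental and regulatory genes of muscle had a median of -0.02 and a mean of 0.11 (adjusted p = 0.422, upward). Myogenin, Myog, read 38.7 ± 26.4 and 81.4 ± 28.3 (SD, n = 3 each) with groups that overlapped, Mef2c stood at 1.22 and the acetylcholine receptor subunit Chrna1 at 0.757. The sarcomere list passed under 4 alternatives (median scaling, array weights, adjacent title numbers as a block, and without knockout replicate 1), with an adjusted p from 0.0262 to 0.88 over all alternatives and a median of up to 0.12. With an estimated correlation these 4 calls were lost (adjusted p = 0.376, 0.342, 0.38 and 0.453). The calcium list passed under 2, with that block and without wild-type replicate 1, in a range of 0.0465 to 0.486, and both calls were lost with an estimated correlation (adjusted p = 0.38 and 0.285). In each of these lists 0 members passed, over the list alone or over all probe sets.

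Mitochondrial energy genes were higher as groups, by small amounts. Of 57 oxidative phosphorylation genes 45 were higher, with a median log2 difference of 0.12 (camera adjusted p = 3.41e-07; adjusted p = 0.285 with an estimated correlation). Cox6a2, the muscle form of a cytochrome oxidase subunit, read 6258 ± 464 and 7539 ± 334 (SD, n = 3 each), Atp5l and Ndufb6 stood at ratios of 1.21 and 1.16, and cytochrome c, Cycs, at 0.746. Of 21 tricarboxylic acid cycle genes 17 were higher, with a median of 0.10 (adjusted p = 0.0125; adjusted p = 0.328 with an estimated correlation), among them Sdhd (1.15), Pdha1 (1.17), Mdh2 (1.11) and Ogdh (1.14). Of 22 glycolysis and glycogen genes 16 were higher, with a median of 0.06 (adjusted p = 0.0137; adjusted p = 0.285 with an estimated correlation), including Pkm (1.22), Aldoa (1.24), Hk2 (1.15) and Eno3 (1.19). Proteasome and atrophy genes had 20 of 28 members higher and a median of 0.08 (adjusted p = 0.0281; adjusted p = 0.285 with an estimated correlation), with the calpains Capn1 and Capn3 at 1.26 and 1.22, Psmb6 at 1.14 and Psmc5 at 0.783. In these lists 0 members passed, over the list alone or over all probe sets. Fatty acid oxidation genes had a median of -0.008 (adjusted p = 0.817), with Decr1 at 0.770, Etfa at 0.825, Etfdh at 0.834 and Fabp3 at 0.901. Lipid synthesis genes had a median of -0.15 (adjusted p = 0.084), with Hmgcs1 at 0.780, Acly at 0.881, Scd1 at 0.692 and Dgat1 at 0.846. That list passed without knockout replicate 2 (-0.21, adjusted p = 0.0364) and with adjacent title numbers as a block (adjusted p = 0.0406), in a range of 0.0364 to 0.383 over the alternatives. Both calls were lost with an estimated correlation (adjusted p = 0.525 and 0.38). The log2 difference of Scd1 ran from -0.95 to -0.068 when single arrays were left out. The median difference over all probe sets also went with signal, from -0.081 in the dimmest of 5 groups to 0.054 in the brightest. Against random lists matched on signal the medians lay at the 91.6 percentile for oxidative phosphorylation, 52.5 for the tricarboxylic acid cycle, 25.4 for glycolysis and 88.9 for the proteasome list. After quantile normalization or cyclic loess, 0 of the 6 higher lists passed, and the glycolysis median turned to -0.021 and -0.027. Median scaling moved the median of all probe sets to 0.051. The medians were then 0.19 for oxidative phosphorylation, 0.16 for the tricarboxylic acid cycle, 0.13 for glycolysis and 0.14 for the proteasome list. These lists passed at the preset correlation, but not with an estimated correlation (adjusted p = 0.376 each). The oxidative phosphorylation list passed whichever array was left out, but the tricarboxylic acid cycle list was lost in 2, glycolysis in 3 and the proteasome list in 3 of 6 such fits. Over these fits the medians ran from 0.090 to 0.13 for oxidative phosphorylation, 0.063 to 0.14 for the tricarboxylic acid cycle, 0.028 (without knockout replicate 3) to 0.086 for glycolysis and 0.024 (without knockout replicate 2) to 0.097 for the proteasome list. These 3 lists were also lost over the 4 arrays sharing a title prefix (adjusted p = 0.161, 0.0657 and 0.28), glycolysis without the filter (adjusted p = 0.0555), and the proteasome list with the stricter filter (adjusted p = 0.0801) and with array weights (adjusted p = 0.0893).

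**Figure D2:**
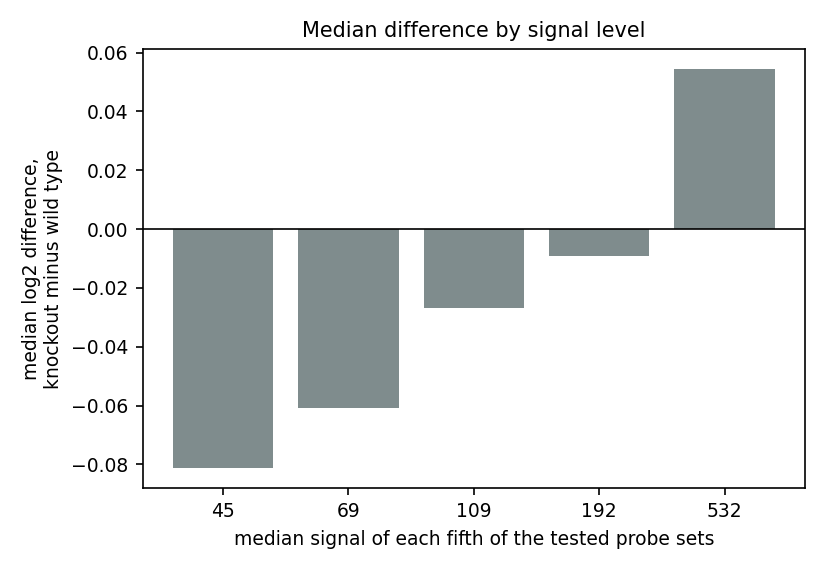
Median log2 difference (knockout minus wild type) of the tested probe sets in 5 groups of equal size by signal, each labelled with its median signal in arbitrary units. The bars go from -0.081 at a median signal of 44.6 to 0.054 at 532.

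Stress, immune and matrix genes were lower as groups in the knockout. Of 29 immediate early and stress genes 24 were lower, with a median of -0.12 (camera adjusted p = 0.00418; adjusted p = 0.285 with an estimated correlation). The transcription factor Atf3 read 168.9 ± 11.2 and 119.6 ± 28.3 (SD, n = 3 each) and the phosphatase Dusp1 1056 ± 216 and 787 ± 19.6, while Klf4 and Ier2 stood at ratios of 0.701 and 0.790. Of 14 inflammation and interferon genes 11 were lower, with a median of -0.19 (adjusted p = 0.0125; adjusted p = 0.285 with an estimated correlation), among them the class I antigen H2-D1 (0.738), Socs3 (0.776), the chemokine Cxcl1 (0.732) and Irf1 (0.824). Of 26 extracellular matrix genes 17 were lower, with a median of -0.08 (adjusted p = 0.0478; adjusted p = 0.308 with an estimated correlation), among them the basement membrane collagens Col4a1 (0.789) and Col4a2 (0.816), Sparc (0.812) and the protease Ctsk (0.761). In these lists 0 members passed, over the list alone or over all probe sets. Without wild-type replicate 3 none of the 3 lists passed (adjusted p = 0.0913, 0.0822 and 0.123). The stress median was nearer 0 in that fit (-0.072), but the inflammation (-0.21) and matrix (-0.11) medians were not. The medians over the fits with an array left out ran from -0.26 (without knockout replicate 2) to -0.072 (without wild-type replicate 3) for stress, -0.29 (without wild-type replicate 1) to -0.13 for inflammation and -0.15 (without knockout replicate 1) to -0.077 for matrix genes. Over the 6 fits with an array left out, the matrix list was lost in 4, the inflammation list in 3 and the stress list in 2. Over all alternatives the stress median ran from -0.27, over the 4 arrays sharing a title prefix, to -0.049 with median scaling. The matrix list was also lost with median scaling (median -0.013, adjusted p = 0.0625), the higher floor (adjusted p = 0.0516), array weights (adjusted p = 0.0949) and over the 4 arrays sharing a title prefix (adjusted p = 0.485). The inflammation list was also lost with array weights (adjusted p = 0.0893) and over those 4 arrays (median -0.067, adjusted p = 0.285). After quantile normalization and after cyclic loess all 3 passed at the preset correlation, and none did with an estimated correlation (adjusted p = 0.62 and 0.679). The medians of the stress, inflammation and matrix lists lay at the 0.05, 0.6 and 0.17 percentiles of random lists matched on signal. The growth factor list had a median of 0.02 and a mean of -0.06 (adjusted p = 0.863, downward), with Ccn1 at 0.677, follistatin Fst at 0.607, Pdgfra at 0.746 and Fgfr1 at 1.13. Sex steroid receptor and estrogen-responsive genes had a median of -0.01 (adjusted p = 0.675), with the coactivators Ncoa1 at 0.744 and Ncoa3 at 0.819, Esrra at 1.15 and Efna1 at 0.811. Antioxidant genes had a median of -0.02 (adjusted p = 0.59), with Gpx3 at 0.730, catalase Cat at 0.849, Prdx4 at 0.735 and Gstm5 at 1.11.

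**Figure D3:**
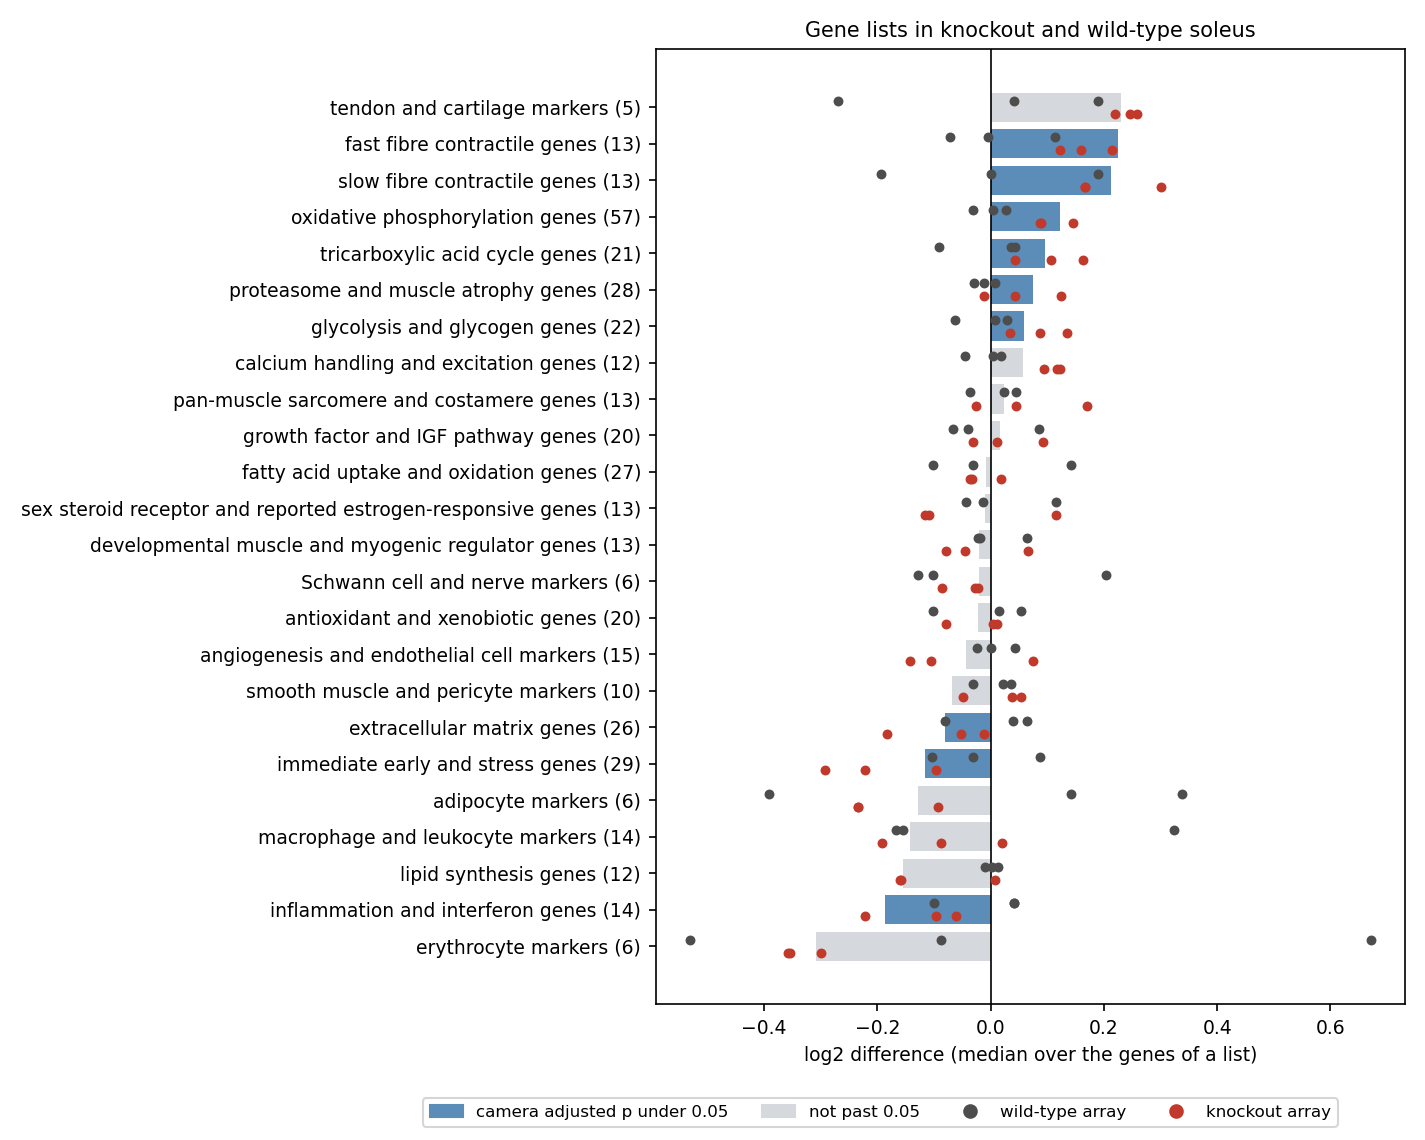
Median log2 difference (knockout minus wild type) of each gene list as bars, with the number of genes tested in brackets; dots are the median over the same genes of each array's value minus the wild-type mean. Blue bars passed camera's adjusted threshold at the preset correlation, from 0.23 for fast fibre genes to -0.19 for inflammation genes, and wild-type and knockout dots overlap for several lists.

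Markers of other cell types did not pass as lists with the settings described above, but were not level between the samples. Red cell markers were lower for 6 of 6 genes, with a median of -0.31 (camera adjusted p = 0.0552), and this rested on wild-type replicate 1: without it the median was -0.012 (adjusted p = 0.616), and without wild-type replicate 2 it was -0.54 (adjusted p = 0.000873). It also passed with median scaling, array weights, adjacent title numbers as a block and over the 4 arrays sharing a title prefix (adjusted p = 0.0262, 0.0171, 0.0406 and 0.0108). With an estimated correlation these 5 calls were lost (adjusted p = 0.408, 0.443, 0.41, 0.565 and 0.531). Hbb-b2, a beta globin, read 505 ± 430 and 253 ± 33.6 (SD, n = 3 each), and Alas2, Car2 and Bpgm stood at ratios of 0.687, 0.720 and 0.908. Macrophage and leukocyte markers had a median of -0.14 (adjusted p = 0.0807), with the class II genes H2-Eb1 at 0.748, H2-Aa at 0.641 and Cd74 at 0.788 and the complement gene C1qb at 0.766. Without wild-type replicate 3 that median was -0.03, and it passed without wild-type replicate 1 (-0.25, adjusted p = 0.00367), without wild-type replicate 2 (-0.30, adjusted p = 0.0193) and without knockout replicate 1 (-0.27, adjusted p = 0.0334), and with the stricter filter (adjusted p = 0.036), in a range of 0.00367 to 0.883 over the alternatives. With an estimated correlation these 4 calls were lost (adjusted p = 0.393, 0.545, 0.55 and 0.479). Adipocyte markers had a median of -0.13 (adjusted p = 0.128), with adiponectin, Adipoq, at 0.535, Lipe at 0.871 and Lep at 0.960. Car3, at 0.819, was also on this list, though its signal in a muscle sample need not come from fat cells. The adipocyte list passed without wild-type replicate 1 (-0.34, adjusted p = 0.00195) and with adjacent title numbers as a block (adjusted p = 0.0406), in a range of 0.00195 to 0.469. Both calls were lost with an estimated correlation (adjusted p = 0.238 and 0.38). Endothelial markers had a median of -0.04 (adjusted p = 0.413), with Cd34 at 0.831, Tek at 0.827, Pecam1 at 0.803 and Fabp4 at 0.710. When single arrays were left out, the log2 difference of Fabp4 ran from -0.78 to -0.072 and that of Pecam1 from -0.44 to -0.12. Tendon and cartilage markers were higher, with a median of 0.23 over 5 genes (adjusted p = 0.128), Chad at 1.17, Fmod at 1.17, Clec3b at 1.20 and Scx at 1.44. They passed over the 4 arrays sharing a title prefix (0.29, adjusted p = 0.0236) and with adjacent title numbers as a block (adjusted p = 0.0406), in a range of 0.0236 to 0.487, and their median was 0.096 without wild-type replicate 1. Both calls were lost with an estimated correlation (adjusted p = 0.531 and 0.38). Schwann cell markers had a median of -0.02 and a mean of 0.02 (adjusted p = 0.869, upward), with Sox10 at 1.39, Egr2 at 0.775, Pmp22 at 0.908 and Mbp at 0.887. Smooth muscle markers had a median of -0.07 and a mean of 0.01 (adjusted p = 0.933, upward), with Smtn at 1.40, Des at 1.08, Rgs5 at 0.909 and Notch3 at 0.924. The skin list was not tested because 2 of its 13 genes were kept, Lor at 1.06 and Sprr1a at 0.925.

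An excess of differing genes in the neighbourhood of Esr2 was neither shown nor excluded. A knockout allele made in cells of another strain can carry flanking DNA, so tested probe sets within 10 Mb of Esr2 were compared with the rest. Of 47 nearby probe sets 3 had an unadjusted p under 0.05 (6.38%), against 298 of 5654 elsewhere (5.27%), an odds ratio of 1.23 with a 95% interval of 0.242 to 3.86 (Fisher's exact p = 0.737, two-sided). The 3 were Six4 at a ratio of 1.64, Numb at 0.642 and Mnat1 at 0.726, with an adjusted p of 0.923 each. Further tested probe sets did not show these differences to the same extent: on the log2 scale that of Mnat1 gave -0.019 and those of Six4 0.25 and 0.04. The odds ratio was 1.63 within 5 Mb and 1.31 within 20 Mb.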

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

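Cyclic loess and the fit of the 4 arrays sharing a title prefix were chosen after seeing the data; the other alternatives were planned. No probe set passed the adjusted threshold under 16 of 19 alternatives. The count was 1 without the filter (Hoxd1, at 4.5 to 11, near the floor), 1 with adjacent title numbers as a block (Myh4), and 0 to 1 when single arrays were left out (Tuba1a without knockout replicate 1, at 1264 there against 423 and 353 in the other knockout arrays). The count at an unadjusted p under 0.01, 55, became 159 without the filter, with more probe sets tested, 33 with the filter at the 70th percentile, with fewer tested, 119 with array weights, 129 over the 4 arrays, and 29 to 85 when single arrays were left out. The 9 gene lists became 3 after quantile normalization, 3 after cyclic loess, 14 with adjacent title numbers as a block, 0 with an estimated correlation, 0 with fry, and 3 to 11 when single arrays were left out (lowest without wild-type replicate 3). With the title prefix as a block 9 of the 9 stayed, and over the 4 arrays 4 stayed, while the other 2 arrays hold 1 sample per group and give no test. Deviations from the group means correlated at -0.0052, 0.035 and -0.0029 between arrays of adjacent title number, so pairing was not shown. The odds ratio near Esr2 turned to 0.650 with median scaling, 0.854 without the filter and 0.703 over the 4 arrays, and ran from 0.701 to 2.07 when single arrays were left out. The floored Esr2 difference, 0.036, was 1.28 with the floor at the 5th percentile, which shows that it depends on values below the floor of 7.8. For the other shifts the cause was not tested.

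Of 452 list values 38 changed the sign of the median, nearly all in lists with a median near 0, and of the named genes' values 15 did. Of the other list values 352 kept direction and side of the threshold, 41 no longer passed and 21 newly passed, and 2259 values of named genes stayed, with 1 newly past. Low signal limits the estrogen receptor genes, whose probe sets all lie below the filter. Quantile normalization gave -0.025 for Myl3, -0.0070 for Tnnt3, 0.020 for the developmental, -0.021 for the glycolysis and -0.00048 for the growth factor list. Median scaling, which moved the median of all probe sets to 0.051, gave 0.0089 for Lep, 0.047 for the developmental, 0.058 for the fatty acid, 0.057 for the sex steroid, 0.046 for the antioxidant, 0.024 for the endothelial and 0.046 for the Schwann cell list. Array weights gave 0.034 for Lep, 0.0042 for the developmental, 0.0089 for the fatty acid and 0.0071 for the Schwann cell list. Cyclic loess gave 0.015 for the developmental, -0.027 for the glycolysis and -0.00012 for the growth factor list. The developmental list stood at 0.020 without the filter, and the sex steroid list at 0.026 with the filter at the 70th percentile. The 4 arrays gave 0.25 for Lep, 0.051 for Pmp22, 0.15 for Mbp, 0.091 for Notch3, 0.064 for Sprr1a, 0.032 for the developmental, 0.012 for the sex steroid, 0.051 for the Schwann cell and 0.034 for the smooth muscle list. Leaving out single arrays gave ranges of -0.22 to 0.14 for Lep, -0.29 to 0.035 for Mbp, -0.20 to 0.028 for Notch3, -0.023 to 1.18 for Scx, -0.089 to 0.22 for Lor, -0.047 to 0.046 for the developmental list, -0.078 to 0.057 for the fatty acid list, -0.046 to 0.044 for the growth factor list, -0.046 to 0.038 for the sex steroid list, -0.074 to 0.036 for the antioxidant list, -0.20 to 0.035 for the Schwann cell list and -0.12 to 0.0031 for the smooth muscle list.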

Other observations

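The tests chosen only after the result was seen were those of the non-muscle cells, of the higher and lower lists apart, of random lists matched on signal in this weighing, of probe set counts among splits and of Myh4. Cyclic loess itself was added once the data had been seen.

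A signal-dependent difference in scale between the arrays may account for lists that were higher in the knockout, since 0 of 6 passed after cyclic loess and their medians shrank from between 0.059 and 0.23 to between -0.027 and 0.076, though the correction would also remove a true rise of the most abundant transcripts. For the slow and fast contractile lists this stays open. Their medians lay at the 99.3 and 99.9 percentiles of random lists matched on signal, against 25.4 to 91.6 for the metabolic and proteasome lists. The matching used 20 groups of genes by signal, though, and the brightest has no upper limit. Slow fibre genes had a median signal of 6660, so their match is coarse. After quantile normalization the slow and fast medians were 0.00075 and 0.0015. Over the whole pattern 3 of 9 lists stayed after cyclic loess. That count lay between the outcomes set beforehand, so the test of the whole pattern did not decide. For the 3 lower lists, set apart after the result was seen, the values argue against a signal-dependent difference in scale as the whole cause. After cyclic loess 3 of 3 passed at the preset correlation, with medians of -0.12 for stress, -0.20 for inflammation and -0.093 for matrix. These were no nearer 0 than before, but none of the 3 lists passed with an estimated correlation (adjusted p = 0.679). Of all lists 3 of 9 stayed without wild-type replicate 3, where the fast (0.23 to 0.13) and stress (-0.12 to -0.072) medians shrank. Other single arrays shrank glycolysis (to 0.028 without knockout replicate 3) and the proteasome list (to 0.024 without knockout replicate 2). The slow fibre median shrank from 0.21 to 0.096 without wild-type replicate 1, though that list still passed there at the preset correlation. The count of 3 of 9 met the outcome set beforehand for a single array as the cause. A fit with 1 array fewer also has less power, so a lost call alone does not show dependence on that array. The inflammation (-0.21) and matrix (-0.11) medians did not shrink without wild-type replicate 3, though both calls were lost. How much of the pattern depends on single arrays therefore stays open.

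A lower share of non-muscle cells in the knockout samples would lower the markers of each type alike, and with arrays as the units tendon markers were instead 0.20 higher and red cell markers 0.30 lower. With the settings described above the tendon list did not pass, however, and the red cell difference rested on wild-type replicate 1. With genes as the units the types differed (permutation p = 0.018), but that test treats genes of a type as independent, and with arrays as the units their spread was not unusual among the splits (exact permutation p = 0.7). A lower share of non-muscle cells, of all or of certain types, and an effect of the knockout itself therefore stay open, and staining of sections would test the first.

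The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 9 lists at the preset correlation and the highest other gave 5, so 1 split, the real one, reached that count, but with an estimated correlation each of the 10 gave 0. At an unadjusted p under 0.01 the real split gave 55 probe sets and the highest other 108, with 4 splits at or above the real count. That highest count came from a split that put both arrays of the smaller title prefix on the same side. Other splits of that kind gave 76, 33 and 51, and a split with 1 of those arrays on each side gave 97. The count thus did not simply follow the prefix. Past the adjusted threshold the real split gave 0 and the highest other 1, where all 10 reach a count of 0 by construction, so this comparison tests nothing.

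Myh4 differed 49.7-fold between the 6 arrays, and Actn3 went with it: Pearson's r of the log2 values was 0.969 (exact permutation p = 0.00139, adjusted over 3 relations 0.00417) and Spearman's rho was 1 (exact p = 0.00278, adjusted 0.00833), with r = 0.957 without the 2 arrays farthest from the median of Myh4. Both genes were taken up because they were lower in the knockout. A shared group difference alone raises a correlation over all 6 arrays, and these p-values do not allow for it. Between adjacent title numbers, the wild-type value of Myh4 was 7.63, 4.64 and 6.77 times the knockout value, but the exact permutation p between the groups was 0.2. One hypothesis is that the wild-type samples held more pieces of a neighbouring muscle rich in type IIb fibres. Another is that the fibres of soleus itself differed. Pvalb, a further transcript of such fibres, went with Myh4 (rho = 0.886, exact p = 0.0333, adjusted 0.05, and Pearson's r = 0.871, exact p = 0.0306, adjusted 0.0458). Without the farthest 2 arrays r was 0.453, over 4 arrays, too few to say whether the relation rests on those 2. Myh7 of slow fibres did not clearly go with Myh4 either way (rho = 0.314, exact p = 0.564, adjusted 0.564, and r = 0.214, exact p = 0.703, adjusted 0.703, with r = -0.21 without the farthest 2). Both hypotheses predict that Actn3 and Pvalb go with Myh4, so the hypotheses are not separated here. Staining of soleus sections for type IIb myosin would separate them. The 4 and 2 arrays of the title prefixes are too few for a correlation within each. In both groups Myh4, Actn3 and Pvalb were highest in replicate 2 and lowest in replicate 3. Replicate 2 of each group carries the smaller title prefix. A difference that goes with the prefix or the title order was therefore not separated from these hypotheses either. A single array does not account for the Myh4 difference, which was -1.81 or further from 0 whichever array was left out.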
